A study of Mus musculus with 6 samples.

How the data were processed

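The data are polyA RNA-seq of mouse GV oocytes, 6 libraries of 10 oocytes each, prepared per the labels' protocols with a QIAseq FX kit for single cells. Genotype and replicate numbers were taken from the labels, giving 3 wild-type and 3 Zar1 knockout libraries on a C57BL/6N background. The authors deposited raw counts per gene, 1 table per library, with no normalization. Per the submitters' processing notes the tools were bcl2fastq 2.20.0.422, cutadapt 2.8, STAR 2.7.8a and HTSeq 0.13.5, and the genome build was mm39. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here. Counts of overlapping genes, of antisense partners and of genes with near-identical copies are therefore uncertain.

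Each table had 53700 gene rows, of which 52093 had a symbol in the name table used here, and rows without a symbol held at most 0.256% of the counts of a library. The summary rows of the counting were kept out of library sizes and tests. Of all reads they counted, 5.52 ± 0.156% in wild type and 4.90 ± 0.0753% in knockout lay outside genes, 4.22 ± 0.0122% and 4.33 ± 0.0818% in more than 1 gene, and 14.6 ± 0.265% and 14.3 ± 0.610% had more than 1 alignment (mean ± SD, n = 3). Gene counts summed to between 32126555 and 39148833 per library. At that depth 10 counts lie below 1 in CPM, and folds of genes near 0 counts rest on few reads. Transcript lengths, GC content, gene biotypes and 3' UTR sequences came from GENCODE release M21, which is built on GRCm38 and not on mm39, and coordinates are therefore not printed.

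Libraries were compared before they were averaged. A chi-square test over genes gave a ratio to its degrees of freedom between 17.2 and 58.9 for pairs of the same genotype, so none was counted as a duplicate. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with the groups, glmQLFit and glmQLFTest, genotype as the only term, two-sided, Benjamini-Hochberg adjusted p of 0.05 over 16473 genes). Standard errors of log2 fold changes were derived from the F statistic as the absolute log2 fold change over its square root. Levels are CPM, gene counts scaled to library size with TMM factors, as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.212. In simulated counts 200 genes were set to change and the same steps were run on 16072 genes. They recovered 35.9% of 39 genes changed 1.5-fold, 58.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold. Of the 133 calls 6.77% were false. Far more genes were called in the data (5499), and recovery depends on how many genes change, so these values do not give the recovery in this comparison.

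A total of 23 gene lists were fixed before the data were examined, with 747 of 748 entries found. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone, and lists with at least 3 measured genes were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 22 lists. Shares of counts and library totals were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries.

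Genes named in the text followed a rule fixed before the data were examined, except Cyp19a1 and the genes named only under Other observations. It takes Zar1 and Zar1l, then the 12 largest rises and the 12 largest falls among called genes with a mean of at least 50 counts in the higher group, no overlap between the groups and a symbol that is neither a predicted model nor a pseudogene. It adds up to 4 called members with the smallest adjusted p from each list, or the 2 members with the smallest p where fewer than 2 pass, and the 5 most abundant genes of wild type.

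Alternatives were RLE, upper-quartile and no scaling factors, 3 other filters on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, leaving out the mitochondrial genome or each library in turn, a stricter adjusted p of 0.01, a test against a 1.5-fold change, camera with an estimated correlation, and fry. A correction that enters each library's lowess trends over transcript GC content and length as offsets was added after the data were seen. It covered 99.7% of tested genes. Tests of 3' UTR elements and of gene families used Python 3.11.15 with scipy 1.17.1, with 100000 permutations where permutations were drawn.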

Results

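PolyA RNA was sequenced from pools of 10 germinal vesicle (GV) oocytes of C57BL/6N mice, with 3 libraries from wild-type and 3 from Zar1 knockout animals. GV oocytes are arrested in meiotic prophase and carry maternal mRNA that is translated later, during maturation. ZAR1 is an oocyte RNA-binding protein, and the series concerns how oocytes keep mRNA in a compartment at their mitochondria. The comparison asks which mRNA levels differed in oocytes that lacked Zar1. Levels are of polyA RNA and relative to the other genes of a library, with no external standard used in the scaling. The median log2 fold change of all tested genes was 0.00745. A gain or loss of total mRNA per oocyte would therefore not show, and rises and falls below are relative. The labels call the libraries biological replicates without saying whether each pool came from a separate animal, so the p-values measure the spread between these pools. Gene counts summed to 39148833, 35358795 and 32126555 in wild-type replicates 1, 2 and 3 and to 35066851, 37946223 and 37253021 in knockout replicates 1, 2 and 3. Genes with at least 10 counts numbered 16376 ± 397 (SD, n = 3) in wild type and 16408 ± 100.01 in knockout, which did not differ in an exact two-sided permutation test (p = 0.9, where 0.1 is the smallest p that 3 against 3 libraries allow).

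Libraries of the same genotype resembled each other more than libraries of different genotypes. Across genes, Spearman correlations of log CPM (gene counts scaled to library size) lay between 0.985 and 0.986 within wild type, between 0.979 and 0.981 within knockout and between 0.953 and 0.958 between the groups. The first principal component held 57.7% of the variance and separated the genotypes. The second held 13.3% and set knockout replicate 3 (score 49.6) apart from knockout replicate 2 (score -34.9), while the wild-type scores lay between -3.94 and 4.57. The biological coefficient of variation was 17.4% among the wild-type libraries and 24.5% among the knockout libraries.

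Zar1 mRNA was almost absent from the knockout libraries. Zar1 (ENSMUSG00000063935.4, protein-coding) had 15245, 13612 and 12810 counts in the wild-type libraries and 69, 96 and 226 in the knockout libraries. Its level fell from 387 ± 8.02 to 3.58 ± 2.28 CPM (mean ± SD, n = 3 each), a 108-fold decrease (log2 fold change -6.75 ± 0.36 SE, edgeR adjusted p = 1.15e-05). The remaining Zar1 reads amounted to 0.511%, 0.666% and 1.5997% of the wild-type mean in knockout replicates 1, 2 and 3. Zar1l (ENSMUSG00000056586.9), the paralog that encodes ZAR2, rose from 123 ± 10.97 to 180.0 ± 11.9 CPM, with every knockout library above every wild-type library (log2 fold change 0.55 ± 0.09, adjusted p = 0.00193). Which part of Zar1 was deleted is not given in the sources used here.

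**Figure D1:**
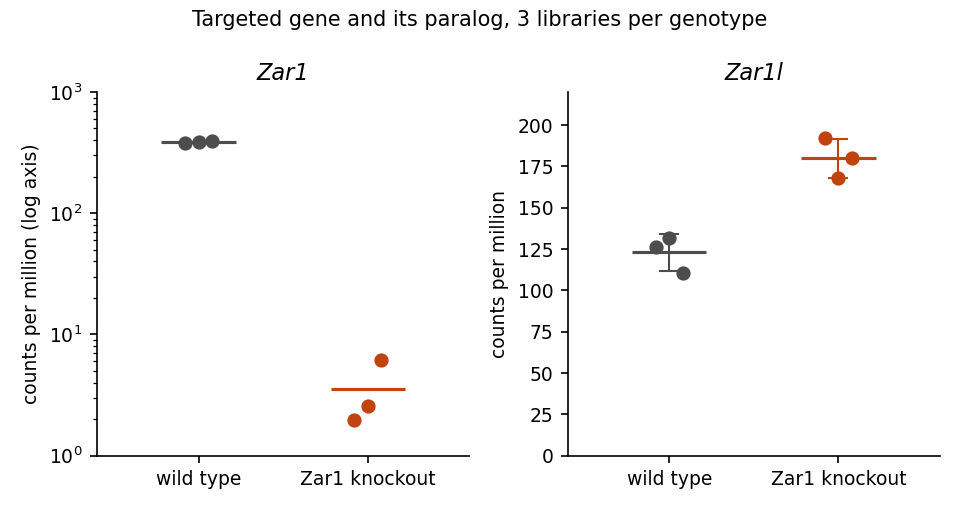
CPM of Zar1 (left, log axis) and Zar1l (right, linear axis) in the 3 wild-type and 3 Zar1 knockout libraries, with points for libraries, horizontal lines for group means and error bars of 1 SD for Zar1l. Zar1 averaged 387 in wild type and 3.58 in knockout, and Zar1l averaged 123 and 180.0.

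Loss of Zar1 was accompanied by changes in 5499 of 16473 tested genes, 33.4% of them. Of these, 2448 rose and 3051 fell in the knockout. The excess of decreases depended on the scaling, with 2811 higher and 2780 lower under upper-quartile factors and 2125 and 3243 with library sizes alone. Changes over 2-fold were more often decreases, with 1443 genes lower and 684 higher. Among 12956 protein-coding genes 2202 rose and 2635 fell, and among 927 long intergenic noncoding RNAs 88 rose and 193 fell. The groups did not overlap in 7871 genes (47.8%), against 10% by chance for 3 against 3 libraries. These are calls of edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Without wild-type replicate 3 the number of genes that rose dropped to 1541, and at a stricter adjusted p of 0.01 there were 1171 higher and 1861 lower. Testing against a 1.5-fold change in place of no change left 417 higher and 1067 lower.

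The largest rises were mostly genes close to silent in wild type. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, went from 2 counts over the 3 wild-type libraries to 1161 over the 3 knockout libraries, a ratio of 561 (95% counting interval 155 to 4641). Its knockout level was 10.7 ± 6.97 CPM (log2 fold change 8.92 ± 0.83), a wide spread between libraries that the counting interval leaves out. The keratin Krt8 rose from 0.269 to 11.1 ± 5.19 CPM (log2 fold change 5.32 ± 0.51), the myosin heavy chain Myh7b from 0.140 to 3.68 ± 2.24, and the zinc finger gene Zfp800 from 0.571 to 10.9 ± 3.37. Dusp5, a phosphatase of ERK kinases, rose by a log2 fold change of 4.20 ± 0.84 to 2.07 ± 1.98 CPM, a spread close to its mean. D7Ertd128e rose by a log2 fold change of 3.87 ± 0.60 and Card9, an adaptor of innate immune signalling, by 3.75 ± 0.43. Krt27 rose by a log2 fold change of 3.66 ± 0.81, the secretory GTPase gene Rab27b by 3.56 ± 0.78 and Itm2a from 15 to 169 counts over 3 libraries. The mitochondrial proline tRNA mt-Tp reached 4.92 ± 6.24 CPM from 0.337, and the cullin gene Cul9 reached 3.55 ± 5.25 from 0.289, so both spreads exceeded the knockout mean. The rise of mt-Tp did not pass limma-voom (adjusted p = 0.0794). Without knockout replicate 2 the log2 fold change of Cul9 was 0.84 (adjusted p = 0.256), and it also missed the threshold without wild-type replicate 1, 2 or 3 (0.12, 0.0923 and 0.112).

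The largest falls reached levels near the detection limit in the knockout. Fer1l6, a ferlin family gene, went from 460 counts over the wild-type libraries to 6 over the knockout libraries, and Slc5a3, the sodium-coupled myo-inositol transporter, from 281 to 4. The count ratios were 79.3 (95% counting interval 36.1 to 217) and 72.6 (28.1 to 268). Lmntd1 fell to a log2 fold change of -5.34 ± 0.77, the RNA-binding protein gene Rbms3 to -4.96 ± 0.48, the transcription factor gene Sox5 to -4.80 ± 0.67 and Prelid2 to -4.68 ± 0.66. Alpl, the tissue-nonspecific alkaline phosphatase, fell from 3.81 ± 1.34 to 0.147 ± 0.0154 CPM, Hdgfl3 from 2.03 to 0.0907, and Pax5, a B-lineage transcription factor, from 5.35 ± 1.30 to 0.249 ± 0.0536. The olfactory receptor gene Olfr283 (-4.39), Tph2, an enzyme of serotonin synthesis (-4.32), and Cntnap5a (-4.11) completed the 12 largest falls, Tph2 having the highest wild-type level at 9.45 ± 0.719 CPM. Counting intervals cover counting error only, since these reads carry no molecular identifiers that were used here.

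**Figure D2:**
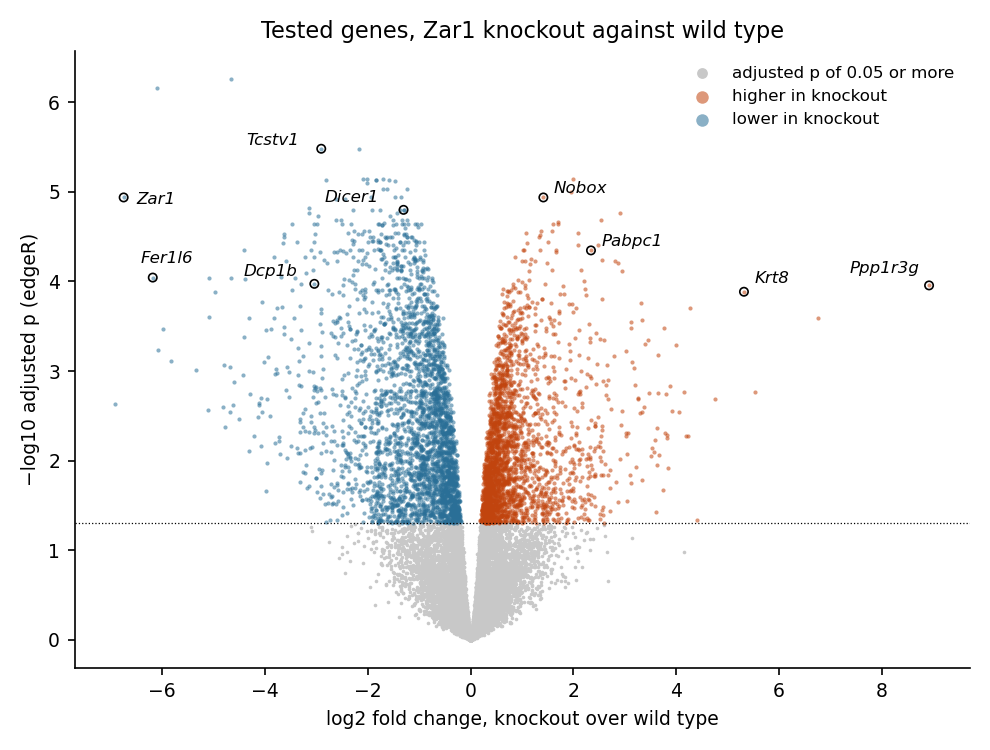
Log2 fold change of knockout over wild type (horizontal axis) against -log10 of the edgeR adjusted p (vertical axis) for the 16473 tested genes, with points for genes, a dotted line at an adjusted p of 0.05 and named genes circled. Zar1 lies at -6.75 and Ppp1r3g at 8.92, and 2448 genes lie above the line on the right and 3051 on the left.

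The most abundant oocyte mRNAs differed by less than 2-fold. Cpeb1, which encodes the protein that binds cytoplasmic polyadenylation elements, was the most abundant in wild type and rose from 6622 ± 390.2 to 9494 ± 879 CPM (log2 fold change 0.52 ± 0.08, adjusted p = 0.00148). Ldhb, the oocyte lactate dehydrogenase subunit, rose from 4528 ± 149.7 to 6729 ± 787, and the mitochondrial ribosomal RNA mt-Rnr2 from 5306 ± 1115 to 8198 ± 1103. Anxa7 rose by 0.25 (adjusted p = 0.0183), a call lost without wild-type replicate 1 (adjusted p = 0.072) or 3 (0.0811). Ooep, a subcortical maternal complex gene, had 5829 ± 433 CPM in wild type and 5629 ± 265 in knockout (log2 fold change -0.05 ± 0.07, adjusted p = 0.635). The 10 most abundant genes took 4.68 ± 0.0354% of counts in wild type and 5.72 ± 0.0911% in knockout, and the 100 most abundant took 20.6 ± 0.332% and 21.99 ± 0.205% (exact permutation p = 0.1 each, the smallest possible).

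Genes for mRNA storage and repression changed in both directions, with 8 of 23 measured members higher, 4 lower and 11 not passing (8 and 4 adjusted over the list alone). The mRNAs of the Y-box proteins, which package maternal mRNA, rose together. Ybx1 went from 775 ± 17.9 to 1135 ± 104 CPM, Ybx3 from 380 ± 22.9 to 575 ± 15.7 and Ybx2, the germ cell form, from 45.5 ± 5.53 to 74.4 ± 2.01. Celf1, a translational repressor and decay factor, fell from 170.3 ± 4.73 to 102 ± 10.6. The list took 1.45 ± 0.0439% of counts in wild type and 1.80 ± 0.0797% in knockout (exact permutation p = 0.1). Cpeb1, its most abundant member, went from 6622 to 9494 CPM and carried most of that rise. Its median log2 fold change was 0.08 (camera adjusted p = 0.487). Without wild-type replicate 3, 5 members rose.

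Of 22 mRNAs that are stored in GV oocytes and translated during maturation, 4 rose, 5 fell and 13 did not pass, the same numbers as adjusted over the list alone. Cdc6, a replication licensing factor, rose from 95.8 ± 5.19 to 216 ± 23.4 CPM (log2 fold change 1.18 ± 0.10). Dcp2, the mRNA decapping enzyme, fell from 105 ± 13.5 to 38.2 ± 2.24 (-1.45 ± 0.11), Spin1, a chromatin reader of oocytes, from 3242 ± 98.8 to 1940.1 ± 125, and the homeobox gene Obox5 from 1289 ± 58.4 to 921 ± 109.7. The median was -0.07 (camera adjusted p = 0.823), and 2 members rose without wild-type replicate 1 or 3 and 7 after a correction for GC content and length. The mRNA decay machinery had 3 of 37 members higher, 10 lower and 24 not passing, again the same adjusted over the list alone. Ythdf3, a reader of methylated adenosine, fell from 189.9 ± 8.82 to 73.2 ± 3.54, Pan3, a deadenylase subunit, from 95.3 ± 4.83 to 49.6 ± 1.86, and the decapping cofactor Dcp1b from 5.31 ± 0.595 to 0.642 ± 0.168. The list's median was -0.03 (camera adjusted p = 0.737), and 5 members rose without knockout replicate 2. After a correction for GC content and length 10 members of the decay list rose.

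Of 13 measured zona pellucida and oocyte-secreted factor mRNAs, 7 rose, 1 fell and 5 did not pass, with 9 and 1 adjusted over the list alone. The zona glycoprotein genes rose together, Zp3 from 1314 ± 117 to 2009.9 ± 56.0 CPM, Zp2 from 1226 ± 117 to 1822 ± 157 and Zp1 from 339 ± 28.4 to 461 ± 20.4. Fgf8, a growth factor secreted to the cumulus cells, rose from 27.8 ± 2.86 to 44.5 ± 5.30. The median was 0.32 (camera adjusted p = 0.0179 with the preset correlation of 0.01; adjusted p = 0.845 with an estimated correlation). The call of Fgf8 did not outlast a correction for GC content and length (adjusted p = 0.0932), and 4 members rose without wild-type replicate 1, 2 or 3. The list took 1.53%, 1.54% and 1.4102% of counts in knockout replicates 1, 2 and 3 and up to 1.4107% in wild type, so knockout replicate 3 lay within the wild-type range (exact permutation p = 0.2). No member fell after the GC and length correction, under upper-quartile factors, or without wild-type replicate 2 or 3 or knockout replicate 1 or 2.

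Oocyte transcription factors had 6 of 15 members higher, 3 lower and 6 not passing (7 and 4 adjusted over the list alone). Their share of counts was 0.672 ± 0.0202% in wild type and lower, at 0.590 ± 0.0693%, in knockout (exact permutation p = 0.3). Knockout replicate 3 (0.670%) lay within the wild-type range. Nobox, a homeobox regulator of oocyte genes, rose from 155 ± 8.16 to 414 ± 18.5 CPM (log2 fold change 1.41 ± 0.07, adjusted p = 1.15e-05). Gtf2a1l, a germ cell TFIIA subunit, rose from 119 ± 8.03 to 203 ± 9.11, Foxr1 from 224 ± 18.7 to 343 ± 30.5, and Figla, an activator of the zona genes, from 12.6 ± 2.13 to 23.7 ± 0.858. The median was 0.17 (camera adjusted p = 0.348, fry adjusted p = 0.0393), and 1 member fell after the GC and length correction, or without wild-type replicate 2 or 3 or knockout replicate 1 or 2. Of 22 subcortical maternal complex and maternal-effect genes 5 rose, 2 fell and 15 did not pass, with equal numbers over the list alone. Padi6 rose from 2079 ± 154 to 3217 ± 124 and Nlrp5 from 723 ± 71.6 to 1030.4 ± 131, while Nlrp4b fell from 698 ± 35.0 to 508 ± 9.34 and the DNA methyltransferase Dnmt1 from 2103 ± 49.4 to 1650.1 ± 75.8. The median was 0.08 (camera adjusted p = 0.487). Nlrp4b lost its call under the GC and length correction (adjusted p = 0.0605), and 3, 3 and 2 maternal-effect members rose without wild-type replicate 1, 2 and 3, and 9 after that correction.

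Meiotic cell cycle and spindle genes had 9 of 39 members higher, 3 lower and 27 not passing (7 and 2 adjusted over the list alone). The kinase genes Aurkb, from 30.4 ± 2.67 to 50.8 ± 1.89 CPM, and Aurka, from 323 ± 15.9 to 403 ± 10.2, rose, as did Fzr1, an activator of the anaphase-promoting complex, from 40.9 ± 0.129 to 65.8 ± 5.56. Pde3a, the oocyte phosphodiesterase whose breakdown of cAMP allows meiosis to resume, fell from 871 ± 60.1 to 572 ± 91.2. The median was 0.09 (camera adjusted p = 0.487), and the list passed after the GC and length correction (adjusted p = 0.0417; adjusted p = 0.553 with an estimated correlation after the correction, 0.887 before it). Without wild-type replicate 1 or 2, 4 and 5 members rose, 1 fell without wild-type replicate 1 or 3, and 5 fell without knockout replicate 3 or in limma-voom with quality weights. In fry the meiotic list passed (adjusted p = 0.0393).

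Chromatin, DNA methylation and imprint genes had 7 of 34 members higher, 10 lower and 17 not passing (8 and 10 adjusted over the list alone). Setd2, a histone H3 methyltransferase, rose from 258 ± 17.5 to 399 ± 23.3 CPM and the oocyte linker histone H1foo from 1964 ± 76.6 to 2531 ± 38.4, while the linker histone H1f0 fell from 77.8 ± 10.7 to 32.8 ± 8.47. The median was 0.06 (camera adjusted p = 0.901), and 2 and 3 members rose without wild-type replicate 1 and 3, while 6 fell after the GC and length correction. Of 20 genes for transposon and small RNA control 3 rose, 5 fell and 12 did not pass, with equal numbers over the list alone. Dicer1, which makes small interfering and micro RNAs, fell from 814 ± 62.8 to 329 ± 7.61 (log2 fold change -1.31 ± 0.07, adjusted p = 1.59e-05). Ago3 fell from 83.7 ± 1.67 to 56.1 ± 2.46 and the piRNA pathway gene Gtsf1 from 692 ± 52.8 to 468 ± 30.6, whereas Mael rose from 39.8 ± 1.98 to 54.7 ± 3.17. The list's share of counts was 0.272 ± 0.00444% in wild type and 0.181 ± 0.00605% in knockout (exact permutation p = 0.1). Dicer1 and Gtsf1 together carried most of that fall. Its median was -0.19 and its mean 0.04 (camera adjusted p = 0.737, direction down; fry adjusted p = 0.015).

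Of 27 genes of the 2-cell stage and zygotic genome activation, 9 were measured. Tcstv1 fell from 86.0 ± 1.27 to 11.5 ± 1.40 CPM (log2 fold change -2.91 ± 0.11, adjusted p = 3.3e-06) and Tcstv3 from 12.2 ± 1.44 to 2.49 ± 0.459. Tcstv1 and Tcstv3 have near-identical copies, and reads with more than 1 alignment were tallied apart from the genes, so their counts are uncertain. Dppa2 rose from 49.7 ± 1.14 to 78.2 ± 3.93 and Zfp750 from 184 ± 7.92 to 273 ± 27.7. In all, 3 rose, 3 fell and 3 did not pass (5 and 3 adjusted over the list alone), with a median of 0.32, a mean of -0.01 and a camera adjusted p of 0.853 (direction up).

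Of 77 nuclear genes of oxidative phosphorylation, 19 rose in the knockout, 2 fell and 56 did not pass (19 and 2 adjusted over the list alone). The complex I subunit Ndufa13 rose from 6.17 ± 0.804 to 14.7 ± 4.09 CPM and the complex II subunit Sdhb from 39.7 ± 3.87 to 61.5 ± 6.82. The members that fell were Atp5g3, a subunit of the ATP synthase membrane ring, from 26.4 ± 0.514 to 10.3 ± 0.573, and Uqcrfs1, the iron-sulfur protein of complex III, from 33.98 ± 1.399 to 19.7 ± 3.18. The median was 0.24 and 64 of the 77 had a positive fold change (camera adjusted p = 0.00164; adjusted p = 0.887 with an estimated correlation). The list lost its call in fry (adjusted p = 0.154) and after the GC and length correction (median 0.16, adjusted p = 0.0849). Without wild-type replicate 2, 10 members rose, and without knockout replicate 3, 32 did; 12 rose after the GC and length correction. The share of counts was 0.616%, 0.639% and 0.558% in knockout replicates 1, 2 and 3 and at most 0.551% in wild type, so replicate 3 lay near wild type.

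All 10 measured mRNAs encoded by the mitochondrial genome had a positive fold change, and 5 passed the test (6 adjusted over the list alone). The complex I subunit mRNA mt-Nd1 rose from 221 ± 43.3 to 454 ± 117 CPM, mt-Nd2 from 39.1 ± 7.76 to 135 ± 121, mt-Co1 from 482 ± 118 to 794 ± 226 and mt-Nd4 from 172 ± 15.2 to 249 ± 65.8. These mRNAs together took 0.126 ± 0.025% of counts in wild type and 0.219 ± 0.0855% in knockout (exact permutation p = 0.1). Knockout replicate 3 was highest at 0.316%, while replicates 1 and 2 had 0.183% and 0.157% and the highest wild-type library 0.154%. The median was 0.70 (camera adjusted p = 0.0286; adjusted p = 0.887 with an estimated correlation). With all libraries 3 members rose in DESeq2 and in limma-voom, where mt-Co1 (adjusted p = 0.0627) and mt-Nd2 (0.0719) respectively missed the threshold, and the list lost its call in fry (adjusted p = 0.128) and with a mean of at least 50 counts (0.0601). Fewer calls were also made when a library was left out: 3 members rose without wild-type replicate 1, 1 without wild-type replicate 2 or 3, and 2 without knockout replicate 3. The calls of mt-Nd2, mt-Co1 and mt-Nd4 were lost without wild-type replicate 2 (adjusted p = 0.0948, 0.0972 and 0.111) or 3 (0.0904, 0.106 and 0.118), and the list's call likewise (0.0532 and 0.0837). Without wild-type replicate 1 mt-Nd2 (0.0617) and mt-Nd4 (0.0587) also missed the threshold, as did mt-Nd4 without knockout replicate 1 (0.0526) and mt-Co1 and mt-Nd4 without knockout replicate 3 (0.0753 and 0.0513). Without a wild-type library the log2 fold change of mt-Nd2 was 1.68 to 1.95, against 1.78 with all libraries. Those fits keep all knockout libraries, where the SD of mt-Nd2 (121) nearly reached its mean (135). They do not show how far a single knockout library carried its rise. In the fits that left out each knockout library in turn, mt-Nd2 kept its direction and its call. The log2 fold changes of mt-Co1 and mt-Nd4 went down to 0.46 and 0.30 without knockout replicate 3, from 0.72 and 0.53.

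Genes for mitochondrial dynamics and genome maintenance moved both ways, with 8 of 43 higher, 8 lower and 27 not passing, and the same numbers over the list alone. Vdac2, an outer membrane channel, fell from 159 ± 3.23 to 68.2 ± 3.91 CPM (log2 fold change -1.22 ± 0.08, adjusted p = 2.31e-05). The mitochondrial DNA-binding protein gene Ssbp1 fell from 34.1 ± 6.61 to 11.7 ± 1.66, the fission adaptor Mief1 from 212 ± 8.17 to 145 ± 7.58, and Nrf1, a transcription factor of mitochondrial genes, from 100.2 ± 5.63 to 65.6 ± 2.91. The median was -0.01 and the mean -0.03, while camera gave the direction up (adjusted p = 0.901). Without wild-type replicate 1 or 3, 5 members rose, and 4 without wild-type replicate 2 or knockout replicate 1. Mitochondrial ribosomal protein genes had 15 of 75 higher, 10 lower and 50 not passing (13 and 10 adjusted over the list alone). Mrps30 rose from 175 ± 10.0 to 277 ± 14.1 and Mrpl58 from 114 ± 10.4 to 199 ± 14.4, while Mrpl50 fell from 21.96 ± 1.29 to 7.01 ± 1.22 and Mrpl17 from 68.1 ± 2.31 to 42.5 ± 0.684. The median was 0.01 (camera adjusted p = 0.675), and 9 members rose without wild-type replicate 1, 2 or 3. Without wild-type replicate 1 or 2 or knockout replicate 1, 6 fell, and 5 without wild-type replicate 3 or after the GC and length correction.

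Cytosolic ribosomal protein mRNAs rose in 33 of 76 measured genes and fell in none; 43 did not pass. Adjusted over the list alone, 42 were higher and 1 lower. Rps15 rose from 112 ± 5.21 to 197 ± 10.2 CPM, Rps3a1 from 141 ± 5.08 to 227 ± 16.1, Rps23 from 15.96 ± 1.89 to 32.9 ± 2.46 and Rpl7a from 129 ± 2.86 to 182 ± 8.41. The median log2 fold change was 0.34 and 67 of the 76 were positive (camera adjusted p = 5.55e-07; adjusted p = 0.887 with an estimated correlation). Reads of these genes can also align to processed pseudogenes, which makes their counts uncertain. Without wild-type replicate 2, 16 members rose, and without replicate 3, 20 did, while 1 fell without wild-type replicate 1 or knockout replicate 1 and with no filter on low counts. After the GC and length correction 21 members rose and 3 fell. The list took 1.03%, 1.08% and 0.936% of counts in knockout replicates 1, 2 and 3 and at most 0.934% in wild type, so knockout replicate 3, which stood apart on the second principal component, lay near wild type.

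Translation initiation and elongation factors had 21 of 42 members higher, 3 lower and 18 not passing (23 and 5 adjusted over the list alone). Pabpc1, the somatic cytoplasmic poly(A)-binding protein, rose from 31.0 ± 8.83 to 157 ± 12.9 CPM (log2 fold change 2.34 ± 0.18, adjusted p = 4.5e-05). The scaffold gene Eif4g3 rose from 159 ± 3.37 to 242 ± 4.63 and Eif1 from 254 ± 2.50 to 386 ± 30.2, whereas Eif4b, a helicase cofactor, fell from 410.4 ± 24.9 to 217 ± 22.2. The median was 0.29 (camera adjusted p = 0.00164; adjusted p = 0.887 with an estimated correlation). Here too knockout replicate 3 lay near wild type, with 0.784% of counts against 0.898% and 0.925% in knockout replicates 1 and 2 and at most 0.761% in wild type. In limma-voom with quality weights 5 members fell. Proteasome subunit genes rose in 12 of 32 and fell in none; 20 did not pass (13 and 1 adjusted over the list alone). Psmc1 rose from 154 ± 3.05 to 216 ± 6.00, Psmd11 from 73.1 ± 2.33 to 105 ± 1.62, Psmc5 from 98.96 ± 12.006 to 162 ± 11.1 and Psmb3 from 19.96 ± 0.663 to 29.2 ± 2.45. The median was 0.19 (camera adjusted p = 0.00427; adjusted p = 0.887 with an estimated correlation), and 6 members rose without wild-type replicate 1 or 2, while 1 fell without knockout replicate 2, with library sizes alone, with a mean of at least 50 counts, in DESeq2 and in limma-voom with quality weights.

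Across the 23 lists 178 of 653 measured members rose and 83 fell. With the preset correlation camera called 6 of 22 lists with at least 3 measured genes, each of them higher in the knockout, and with an estimated correlation it called 0, while 8 passed fry in one direction. Members that rose numbered 109 without wild-type replicate 2 and 114 without wild-type replicate 3.

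**Figure D3:**
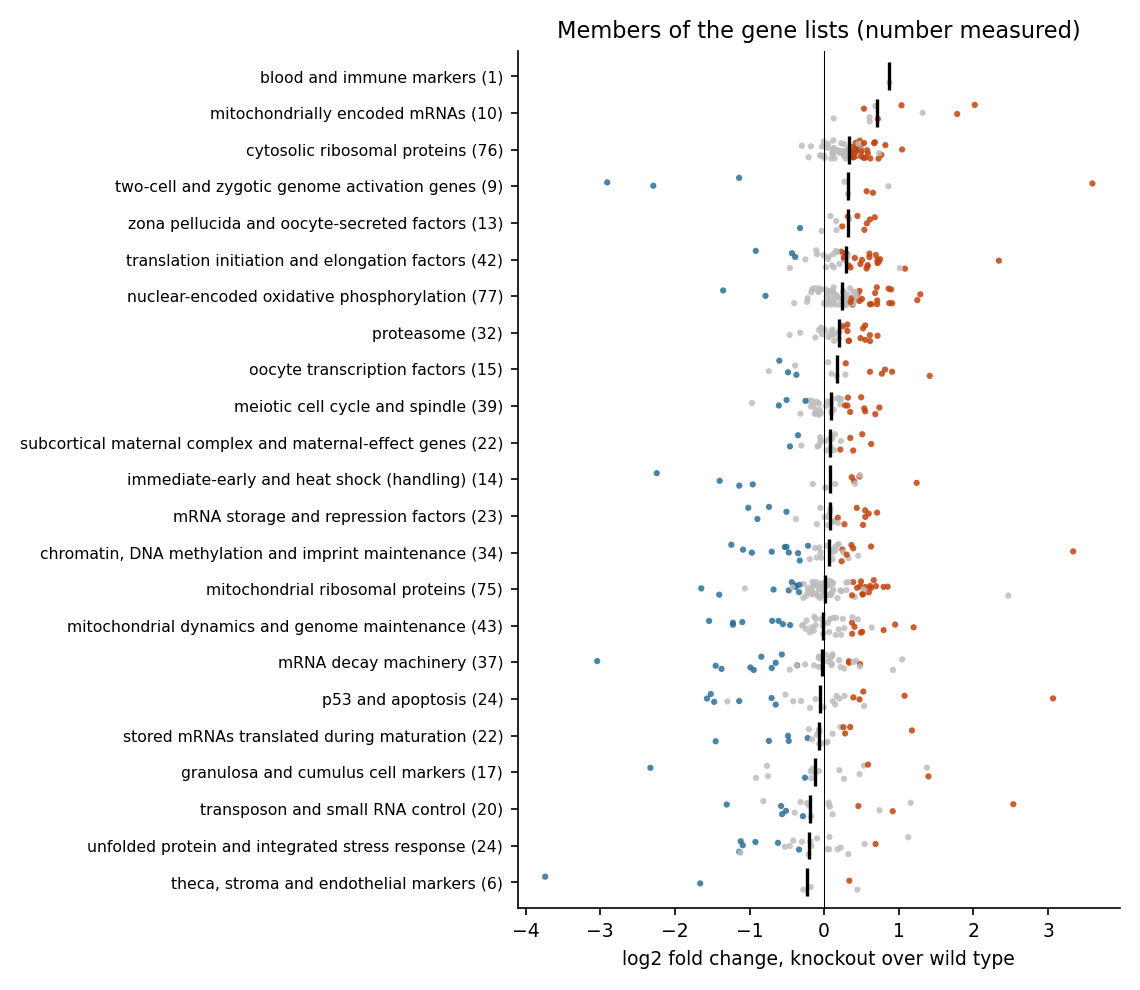
Log2 fold change of knockout over wild type (horizontal axis) for the measured members of each gene list (vertical axis, number measured in brackets), with red points for members called higher, blue for lower, grey for neither, and black bars at list medians. Cytosolic ribosomal proteins have a median of 0.34 with 33 of 76 members called higher and none lower, and most other lists hold members on both sides of 0.

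Stress genes moved in both directions. In the unfolded protein and integrated stress response 1 of 24 rose, 6 fell and 17 did not pass, with equal numbers over the list alone. Atf4, the transcription factor of the integrated stress response, fell from 191 ± 18.0 to 87.9 ± 5.18 CPM, the mitochondrial chaperone Hspa9 from 264 ± 11.4 to 139 ± 8.07 and the endoplasmic reticulum chaperone Hspa5 from 174 ± 10.8 to 113 ± 10.4, while the phosphatase subunit Ppp1r15a rose from 31.0 ± 3.48 to 50.05 ± 1.81. The median was -0.20 (camera adjusted p = 0.487, fry adjusted p = 0.00119), and 3 members fell without wild-type replicate 2, while 2 rose without wild-type replicate 3 or knockout replicate 3, under upper-quartile factors and in limma-voom with quality weights. Of 24 p53 and apoptosis genes 5 rose, 6 fell and 13 did not pass, the same over the list alone. Cdkn1a, a cell cycle inhibitor, rose from 0.182 ± 0.112 to 1.56 ± 0.846 and Bax from 2.85 ± 0.469 to 6.01 ± 1.61, whereas the survival gene Mcl1 fell from 8.55 ± 0.209 to 2.88 ± 0.0701 and Btg2 from 27.6 ± 5.40 to 17.6 ± 1.71. The median was -0.06 (camera adjusted p = 0.894), and Bax lost its call under the GC and length correction (adjusted p = 0.0678). Without wild-type replicate 1, 3 of these members fell, and likewise without wild-type replicate 2 or 3 or knockout replicate 2. Those that rose numbered 3 without wild-type replicate 1 or knockout replicate 3 and 2 without wild-type replicate 3.

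Immediate-early and heat shock genes, which respond to handling, had 4 of 14 higher, 4 lower and 6 not passing, the same over the list alone. Hspa8 rose from 251 ± 11.5 to 348 ± 14.6 CPM and Dnajb1 from 216 ± 26.8 to 285 ± 17.4, while Hspa1b fell from 14.95 ± 2.05 to 7.70 ± 0.553 and Fosb from 3.19 ± 0.630 to 1.21 ± 0.196. The median was 0.08 and the mean -0.17 (camera adjusted p = 0.885, direction up). The call of Dnajb1 was lost without wild-type replicate 2 or 3 (adjusted p = 0.06 and 0.066). Without wild-type replicate 1 or 2 or knockout replicate 3, 2 members rose, and 1 without wild-type replicate 3; 2 fell without wild-type replicate 2 or 3. After the GC and length correction 2 rose.

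Most markers of other ovarian cells were at low levels in both genotypes, with Serpine2, Nr5a2 and Cyp19a1 (48.3 and 42.3 CPM without TMM factors) as exceptions among the granulosa and cumulus markers. Granulosa and cumulus markers took 0.0634 ± 0.00189% of counts in wild type and 0.0558 ± 0.00463% in knockout (exact permutation p = 0.1), and 16 of the 25 lay under 1 in CPM in wild type. Of 17 measured, 2 rose, 2 fell and 13 did not pass (2 and 1 adjusted over the list alone). Nr5a2 rose from 51.8 ± 3.17 to 77.9 ± 5.50 CPM and the hyaluronan synthase Has2 from 1.74 ± 0.354 to 4.61 ± 1.47, while Kitl, the ligand of the oocyte receptor KIT, fell from 4.02 ± 0.321 to 0.797 ± 0.472. Serpine2 had 509 ± 24.3 in wild type and 426 ± 44.3 in knockout (adjusted p = 0.0496), which passed in no fit that left out 1 of the 6 libraries (adjusted p from 0.0539 to 0.15), nor after the GC and length correction (0.127), with RLE or upper-quartile factors (0.0565 and 0.0841), in DESeq2 (0.05001) or in limma-voom with quality weights (0.0502), leaving 1 member lower. The median was -0.12 (camera adjusted p = 0.957). Of 6 measured theca, stroma and endothelial markers 1 rose, 2 fell and 3 did not pass, the same over the list alone. Pdgfra fell from 71 counts over the wild-type libraries to 5 over the knockout libraries. Vwf fell from 83 to 26 counts and Pecam1 rose from 24.2 ± 0.611 to 30.5 ± 2.15 CPM, calls that were lost without wild-type replicate 1 (adjusted p = 0.0573 and 0.107) or 2 (0.0632 and 0.112), for Vwf also without knockout replicate 2 (0.0531) and for Pecam1 without wild-type replicate 3 (0.0939) or knockout replicate 1 or 3 (0.0527 and 0.069). None of these markers rose with library sizes alone, with no filter or with the replicate number as a block, where Pecam1 missed the threshold (edgeR adjusted p = 0.0544, 0.104 and 0.0673). None fell with a minimum CPM of 1 or a mean of at least 50 counts, filters that remove Pdgfra and Vwf. The list's median was -0.23 (camera adjusted p = 0.78). Of 13 blood and immune markers only Cd68 was measured, at 0.779 ± 0.427 and 1.41 ± 0.752 (adjusted p = 0.225), so none was called in the full list or adjusted over the list alone.

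Fold changes followed the GC content and the 3' UTR length of the mRNA. When protein-coding genes were divided by transcript GC content into 5 groups of equal size, the median log2 fold change was -0.20 in the group with a median GC of 41.8% and 0.23 in the group with 57.8%. In the former 9.58% of genes rose and 31.8% fell, and in the latter 26.8% rose and 8.85% fell. Over 3' UTR length the median went from 0.14 in the shortest group (median 160.0 nt) to -0.18 in the longest (median 3410.0 nt), with 11.9% and 31.8% of genes lower. The ribosomal protein mRNAs, with a median length of 858 nt and a GC content of 51.8%, lie on the side that rose. After a GC and length correction chosen after the data were seen, 2578 genes were higher and 2574 lower. The share of reads outside annotated genes was 5.52 ± 0.156% in wild type and 4.90 ± 0.0753% in knockout (exact permutation p = 0.1).

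**Figure D4:**
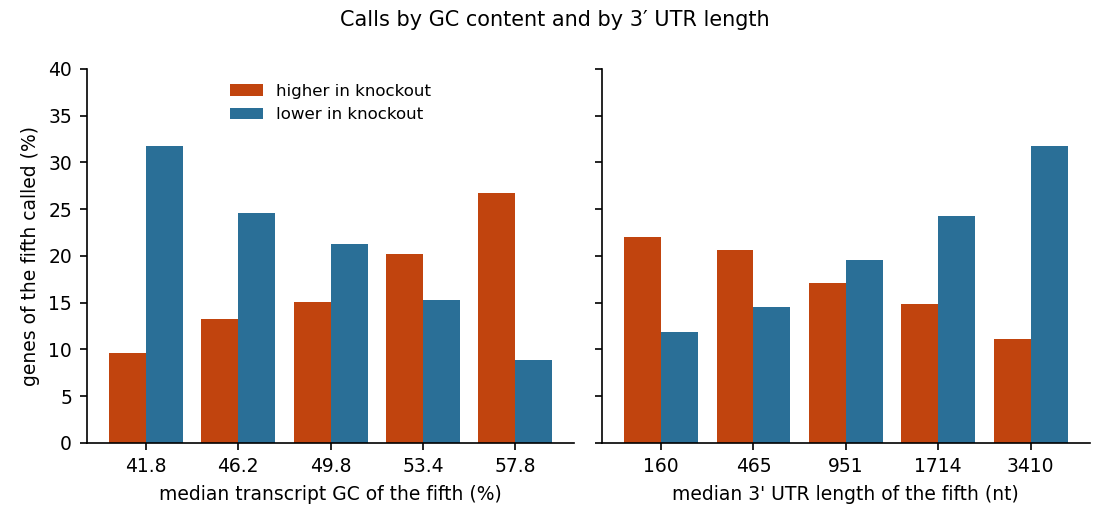
Percent of protein-coding genes called higher (red) or lower (blue) in the knockout, in 5 equal groups by transcript GC content (left, median percent under each pair of bars) and by 3' UTR length (right, median nt). At the lowest GC content 31.8% were lower and 9.58% higher, and at the longest 3' UTRs 31.8% were lower and 11.1% higher.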

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

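The comparison in this part was planned, and no test was chosen after its result was seen. Reads that overlapped more than 1 gene, which enter no gene's count, made up 4.33 ± 0.0818% of the counted reads in knockout and 4.22 ± 0.0122% in wild type (mean ± SD, n = 3). They stood out because the share of each knockout library (4.29%, 4.27% and 4.42% in replicates 1, 2 and 3) lay above that of each wild-type library (highest 4.24%). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.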

How the results depend on the processing

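Among the alternatives in this part, the GC and length correction alone was chosen after the data were seen. No gene called in both the reported fit and another setting changed direction. Counts of higher and lower genes stayed within 1.5 times of 2448 and 3051 under 3 other scalings, 3 other filters, DESeq2, both limma-voom fits and without the mitochondrial genome, but decreases outnumbered rises under each of these except upper-quartile factors (2811 and 2780). At an adjusted p of 0.01 they were 1171 and 1861, and against a 1.5-fold change 417 and 1067, both stricter by construction. Leaving out 1 library gave 1541 to 2509 higher (lowest without wild-type replicate 3) and 2285 to 3125 lower genes. List members that rose then numbered 109 to 199 and those that fell 62 to 83, the lowest without wild-type replicate 2. Fewer libraries were tested in these fits. After the GC and length correction 2578 genes were higher and 2574 lower, of which 1939 and 2384 were called in the reported fit as well. Ooep, not called, had a log2 fold change of 0.0529 there in place of -0.05 (adjusted p = 0.628), and the cause was not tested. In the set test 0 lists passed with an estimated correlation and 21 passed fry's mixed test, which asks another question. The other settings gave 5 to 8 lists. The share of the 10 most abundant genes differed by 0.796 percentage points over nuclear genes and by 1.04 over all genes, because mt-Rnr2 is among the 10. Of 2040 values for named genes under alternatives 1989 kept direction and call and 50 missed the threshold. Replicate numbers are shared between the genotypes, but same-numbered libraries did not deviate together (correlations -0.009, -0.042 and -0.0252). With the replicate number as a block 2078 genes were higher and 2760 lower, of which 2001 and 2694 were called without it. Depth limits the genes near 0 counts, where 6 or fewer counts remain in a group.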

Other observations

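Among the tests in this part, the split count, the granulosa marker test, the tests of GC slopes and the GC and length correction with the tests made on it were chosen after the result was seen. Zinc finger genes with Zfp symbols were lower in the knockout as a family. Of 303 tested members 92 fell and 30 rose, with a median log2 fold change of -0.25 (Wilcoxon rank-sum test across genes, adjusted p = 2.33e-08 over 80 families with at least 15 members; genes are not independent replicates). Examples chosen after their values were seen are Zfp655, which fell from 873 ± 25.7 to 518 ± 37.8 CPM, Zfp473, from 61.1 ± 7.35 to 15.8 ± 2.23, Zfp770, from 14.7 ± 1.23 to 3.404 ± 0.326, and Zfp41, from 7.20 ± 1.18 to 0.508 ± 0.161 (mean ± SD, n = 3). Solute carriers were lower as well, with 66 of 256 down, 31 up and a median of -0.12 (Wilcoxon adjusted p = 0.0408). Whether this family follows the trends over GC content and 3' UTR length was not tested. Examples of members that fell, chosen after their values were seen, are Slc33a1, the acetyl-CoA transporter, from 12.1 ± 1.33 to 1.17 ± 0.345 CPM, and Slc16a1, a monocarboxylate transporter, from 45.9 ± 6.09 to 14.1 ± 1.45. Slc45a3 fell from 1053 ± 28.9 to 788 ± 18.6, while among the 31 that rose Slc38a8 went from 100.3 ± 4.56 to 164 ± 4.22. The ribosomal protein families Rpl and Rps were the others that passed, both higher (adjusted p = 0.00169 each).

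Several keratin genes were expressed above their wild-type level, although the family as a whole did not pass (18 genes, 6 higher, 1 lower, adjusted p = 0.644). Krt25 rose from 3.83 ± 0.581 to 28.8 ± 3.68 CPM and Krt73 from 6.56 ± 1.10 to 36.4 ± 6.71, examples chosen after their values were seen, beside Krt8 and Krt27. Of the other called members, Krt12 and Krt84 rose by log2 fold changes of 0.56 and 0.68, and Krt88 fell to -1.56 ± 0.47.

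The fold change rose with GC content in every knockout library against every wild-type library. The slope of log2 expression over GC content was -0.104 ± 0.00248 per 10 points in wild type and 0.104 ± 0.0166 in knockout (deviations from the mean of the 6 libraries). The difference between genotypes was 6.50 times the larger range within a genotype, which argues against variation between single libraries as the cause. Of the knockout libraries 0 had a slope within the wild-type range, so a difference in preparation between the groups and an effect of genotype cannot be told apart, because no label gives a batch that crosses the genotypes. In a regression over 12571 genes with a 3' UTR, its length had the largest coefficient (-0.13 ± 0.01 per SD) and coding length a coefficient of 0.00 ± 0.01, and the model held 4.59% of the variance of fold changes.

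The rises of ribosomal protein, translation factor, oxidative phosphorylation and proteasome mRNAs may in part follow that trend. Against genes matched on transcript length, GC content and abundance, the median excess in log2 fold change was 0.16 ± 0.04 (bootstrap SE) for ribosomal proteins. It was 0.24 ± 0.08 for translation factors, 0.12 ± 0.04 for oxidative phosphorylation and 0.10 ± 0.06 for the proteasome. The bootstrap drew genes as if they were independent, so these SEs leave out the spread between libraries. After the GC and length correction ribosomal proteins (median 0.18 from 0.34, camera adjusted p = 0.0101) and translation factors (0.32 from 0.29, 0.00106) passed, though not with an estimated correlation (adjusted p = 0.747 and 0.553 after the correction, 0.887 for both before it), and their mean corrected level was higher in each knockout library than in each wild-type library (differences 0.25 ± 0.06 and 0.39 ± 0.05, SE across libraries). No excess lay above 0.1 by 2 SE, the bound set beforehand. By a rule set after the first results, ribosomal proteins and translation factors kept a rise beyond transcript GC content and length. 3' UTR length was neither matched nor corrected for, so a trend over it stays open as the cause. Transcript GC content and length stay open too for oxidative phosphorylation. Its excess lay over 2 SE from 0, but its call was lost after the correction (median 0.16, camera adjusted p = 0.0849). Its corrected difference was 0.18 ± 0.07, with knockout replicate 3 (0.0482) within the wild-type range (highest 0.0557). They stay open for the proteasome as well, whose excess lay within 2 SE of 0. The proteasome passed after the correction (0.16, camera adjusted p = 0.0228, or 0.553 with an estimated correlation), with each knockout library above each wild-type library (0.24 ± 0.04). RNA of cumulus cells also stays open for ribosomal proteins. The 16 markers under 1 in CPM in wild type summed to 1.02 ± 0.467 times the wild-type level, an SE too wide to decide. The whole marker list did not rise: it took at most 0.0589% of counts in knockout libraries and at least 0.0613% in wild-type libraries. Serpine2 was its most abundant marker, at 515 and 420.1 CPM in wild type and knockout without TMM factors, so that share follows mainly 1 gene.

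The Zar1 reads left in the knockout may come from wild-type RNA, from reads assigned to the wrong library or from a shortened Zar1 transcript of the knockout allele. If carry-over made them, no gene in knockout replicate 3, which had the most, should lie below the same 1.55% of its wild-type level (here without TMM factors). Among 8115 genes with at least 5 counts needed, 0 lay below it beyond their 95% Poisson limits. Tph2 (1.12%), Gm30564 (0.861%) and Cyp2c53-ps (1.47%) came closest, with upper limits of 2.87%, 2.52% and 2.30%. The sources of these reads cannot be told apart, since few genes fell far enough to test it.

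A hypothesis for the lower mRNAs was the loss of transcripts that carry a ZAR1 target element or a cytoplasmic polyadenylation element in the 3' UTR. Among 12615 genes those with the ZAR1 element had a mean log2 fold change 0.19 below those without, and their 3' UTRs were longer (median 1983 against 552 nt). Without strata the difference was -0.20 for the polyadenylation element, and -0.16 and -0.21 for the reversed ZAR1 and polyadenylation elements. Within strata of 3' UTR length and GC content the difference was -0.0135 ± 0.0187 (permutation p = 0.471), and for the polyadenylation element 0.0186 ± 0.0197 (permutation p = 0.345; 100000 permutations each). Both lie above the decrease of 0.1 that had been required, by more than 2 SE. For the reversed elements the differences were 0.0231 ± 0.0181 and 0.00929 ± 0.0201. Within these strata, mere presence of either element thus did not go with a lower mean fold change. The ZAR1 element lay in 38.2% of the 3' UTRs and its reversed form in 41.1%, and the polyadenylation element in 59.7% against 61.0%. Binding was not measured, so loss of a bound subset cannot be judged from these means. Zfp mRNAs lay -0.13 ± 0.05 (bootstrap SE over genes) from matched genes and kept a median of -0.15 after the GC and length correction. The mean corrected fold change of the 303 Zfp genes lay below that of 12637 other protein-coding genes (difference -0.16 ± 0.05, permutation p = 0.00075 with 100000 permutations across genes). Camera on the corrected values gave p = 0.0335 with the preset and p = 0.0271 with an estimated correlation, by limma. Their mean corrected level was lower in each knockout library than in each wild-type library (difference -0.14 ± 0.02, SE across libraries). A decrease beyond transcript GC content and length thus remained after the correction. The difference from matched genes was not below -0.1 by 2 SE, the bound set beforehand. Zfp had the smallest p of the 80 families tested on these same libraries, and the permutation and camera p-values are not adjusted for that choice. 3' UTR length was neither matched nor corrected for, so a trend over it stays open as the cause.

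Other results are given as values. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; 1 split, the real one, called 5499 genes and the highest of the others called 0. Among the 100 tested genes nearest to Zar1, 15 were called with a change over 2-fold, against 12.9% of the other genes (odds ratio 1.19, 95% interval 0.638 to 2.08, Fisher's exact test p = 0.548).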
